A study of Homo sapiens with 26 samples.

How the data were processed

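RNA was measured in 26 libraries of 9 lines made from MDA-MB-231Luc, a derivative of the human triple-negative breast cancer cell line MDA-MB-231. Per the labels' protocols, the cells grew in MEM with serum under normoxia and in doxycycline, RNA was extracted with a column kit, and libraries were made from 500 ng of total RNA with the KAPA mRNA Hyper Prep kit for Illumina sequencing. Per the submitters' processing notes, HISAT2, SAMtools and Partek were used with the human build hg19. Their versions, the annotation, the strand setting and the rules for reads that match several genes are not given in the sources used here. The authors deposited 1 table of RPKM values, read numbers scaled by transcript length and mapped library total, with 33562 gene symbols in rows and 1 column for each of the 26 libraries. RPKM values are already scaled to a total and a transcript length, so they cannot serve as counts.

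The deposited RPKM values give no library totals. For a gene of known length the value of 1 read falls with depth, so the commonest value times transcript length among low genes was used to estimate depth, with GENCODE transcript lengths used for this purpose alone and found for 19602 rows. It gave 12200000 to 20300000 reads or fragments per library, with a median of 18500000 in the libraries lettered A to H and 14900000 in those lettered I to Z. Of the 542686 values above 0, 25606 (4.72%) lay under 1e-04, below what 1 read is worth, so values this small were read as 0 in all but name. With these depths genes near 1 RPKM carry the largest counting error. No coordinates are printed because the reference used here is of another build than the table.

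Samples were grouped by the labels. Empty, NES-Empty and NLS-Empty are 3 control lines without AURKA cDNA. WT-AURKA (clones c1 and c2), NES-AURKA (clones c1 and c2) and NLS-AURKA (clones c2 and c3) are 6 lines with AURKA cDNA and no added signal, a nuclear export signal or a nuclear localization signal. WT-AURKA c2 has 2 libraries and the other lines have 3 each. Control lines are labelled with the guide sgCon and passages 19 to 20, and the AURKA clones with a guide against AURKA and passages 32 to 35. WT-AURKA and NES-AURKA clones share 1 guide and cDNA label and NLS-AURKA clones carry another of each. Guide, passage and clonal derivation are therefore confounded with the presence of AURKA cDNA, and guide and cDNA label with the nuclear signal. The titles letter 1 library of 8 lines A to H and the others I to Z, and these letter sets were treated as possible batches.

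The design fixed before the data were examined assumed counts and named limma as the test for normalized values. The test used here was therefore limma (version 3.58.1, R 4.3.3) on log2(RPKM + 1) with a mean-variance trend in the empirical Bayes step. A gene was tested if it reached 1 RPKM in at least 2 libraries, which left 12589 genes. Fold changes are on the log2(RPKM + 1) scale, which understates the change of low genes. Differences between constructs were tested on 1 value per line, the mean of log2(RPKM + 1) over its libraries, because the line is the unit that was made separately, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. AURKA lines against control lines used a fit with 2 arms, and the contrasts between constructs a fit with 4 groups (control, WT, NES and NLS). Single lines were compared in a fit to the 26 libraries with 1 coefficient per line, where a call also needed an absolute log2 fold change of at least 1. In that fit, p-values measure the spread between libraries of a line, which includes the difference between letter sets unless a letter-set term is added. The labels do not say whether libraries of a line came from separate cultures, so that spread may be technical.

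Before the data were examined, 32 gene lists were written, and 30 of them had enough tested genes for a set test. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the lists within a contrast. Every list that camera called is described, together with the HIF target, Aurora A partner, mitosis and breast cancer metastasis lists. The genes named were also chosen by a rule fixed in advance. It takes AURKA, AURKB, TPX2, HIF1A, VEGFA, CA9, VIM and CDH1. For each contrast between groups of lines it adds the 10 highest and 10 lowest called fold changes with a mean of at least 5 RPKM in the higher group and the same sign in every pairing of lines, and it adds up to 4 members of each described list. The floor of 5 RPKM stands in for the limit of 5 written in scaled counts for a count table. For the clones against their matched control it takes the 5 genes at either end, and for single clones or control lines the 3 at either end. CA9 did not reach the filter and was not tested, and some genes that the rule takes are not reported here.

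Alternatives fixed before the data were examined were a robust empirical Bayes step, a pseudocount of 0.1, no filter, a filter of 10 RPKM, the I to Z libraries alone, a letter-set term, the line as a random block, matched control lines, no fold threshold, and leaving out each line or library in turn. The fit with matched control lines gives each control line and each construct its own term. Its spread comes from the 3 pairs of clones alone and leaves out that between control lines and between constructs. Median-of-ratios scaling of the RPKM values, letter-set-adjusted line values, fits without the libraries lettered D and A, and fits to the A to H libraries alone were chosen after seeing the data, as were the I to Z libraries alone for single-line comparisons. No replicate number is shared between groups in the labels, so no paired fit was made. The steps were tested on simulated data with 12589 genes, of which 200 were changed. The simulated values were independent between genes and between lines or libraries, without letter sets or a shared origin of clones. The shares recovered and false therefore need not hold for the real data. For NLS-AURKA against NES-AURKA, 14.5% of genes changed by 0.5 on the log2 scale were recovered, 87.5% of those changed by 1 and 97.5% of those changed by 2. Of the calls 6.45%, 2.78% and 6.25% were false. For AURKA lines against control lines the shares were 22%, 83% and 99%, and 12%, 7.26% and 5.26% of the calls were false. For NLS-AURKA clones against NLS-Empty in both clones the shares were 0%, 21.5% and 89.5%, and 0% and 1.1% of the calls were false at changes of 1 and 2.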

Results

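Gene expression was measured by RNA sequencing in 26 libraries from 9 lines of MDA-MB-231Luc, a derivative of the triple-negative breast cancer cell line MDA-MB-231. The lines differed in the compartment to which AURKA, a serine/threonine kinase that drives centrosome maturation and spindle assembly, was directed. The study set these profiles beside the metastatic behaviour of the cells in xenografts, which is not analysed here. The 3 control lines carried the doxycycline-inducible vector without AURKA cDNA, and 6 clones carried AURKA cDNA without a signal (WT-AURKA), with a nuclear export signal (NES-AURKA) or with a nuclear localization signal (NLS-AURKA), with 2 clones of each construct. Estimated depth was 12200000 to 20300000 reads or fragments per library.

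The 8 libraries lettered A to H stood apart from the 18 lettered I to Z. MALAT1, a nuclear long non-coding RNA, was at 174.6 to 561 RPKM in the first set and 6.11 to 33.5 RPKM in the second, and NEAT1, the RNA scaffold of paraspeckles, at 6.02 to 31.3 RPKM and 0.331 to 1.10 RPKM. Between 22229 and 24418 genes had a value above 0 in the A to H libraries and between 19157 and 20759 in the others. The ribosomal RNA row CH507-513H4.3 was at 20520 to 27840 RPKM in the A to H libraries, up to 15.9% of a library's RPKM sum. In the I to Z libraries it was at 1437 to 26070 RPKM, with both extremes in NLS-AURKA (libraries Z and X). Component 1 of a principal component analysis held 38.5% of the variance and component 2 held 22.1%. Some results are also given for the I to Z libraries alone, 2 per line. The A to H set holds 1 library of each line except WT-AURKA c2. A fit to these 8 libraries, chosen after seeing the data, called 1455 genes between AURKA and control lines, 986 between NLS-AURKA and NES-AURKA, 387 between NLS-AURKA and WT-AURKA and 0 between NES-AURKA and WT-AURKA. Of these, 1080, 887 and 325 were also called in the pooled fit. WT-AURKA is library D alone in that fit, so its spread is taken from the other groups.

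**Figure D1:**
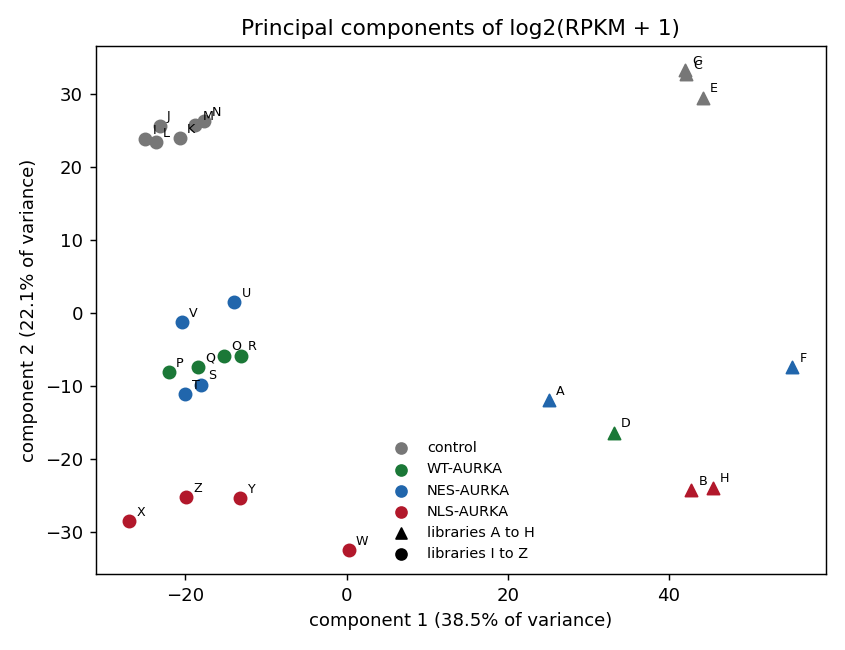
Principal components of log2(RPKM + 1) for the 26 libraries, one point per library with its letter (grey control, green WT-AURKA, blue NES-AURKA, red NLS-AURKA, triangles libraries A to H, circles I to Z). Component 1 holds 38.5% of the variance and component 2 holds 22.1%.

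AURKA itself was at 57.0 ± 6.29 RPKM (SD, n = 3 lines) in the control lines, 25.3 ± 16.6 RPKM (n = 2) in WT-AURKA, 28.2 ± 5.17 RPKM (n = 2) in NES-AURKA and 59.2 ± 10.4 RPKM (n = 2) in NLS-AURKA. NLS-AURKA lay above WT-AURKA by 1.52 on the log2 scale (SE 0.26, limma adjusted p = 0.00218) and above NES-AURKA by 1.0 (SE 0.26, adjusted p = 0.0167). Within the I to Z libraries these differences were 1.82 (adjusted p = 0.00196) and 0.93 (adjusted p = 0.0390), and in the A to H libraries, where library D is the only one of WT-AURKA, -0.35 (adjusted p = 0.623) and 1.16 (adjusted p = 0.0652). The second did not pass without NES-AURKA c2 (0.80, adjusted p = 0.0568), without NLS-AURKA c2 (0.85, adjusted p = 0.118) or with no filter on low genes (adjusted p = 0.0883). NES-AURKA and WT-AURKA differed by 0.52 (SE 0.26, adjusted p = 0.272), and all AURKA lines against control lines by -0.86 (SE 0.39, adjusted p = 0.145; I to Z, -1.26, adjusted p = 0.0862). That last difference passed without NLS-AURKA c2 (-1.06, adjusted p = 0.0479). It also passed against matched control lines (adjusted p = 0.0179), a fit that leaves out the spread between control lines and between constructs.

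Libraries of some lines were far apart in AURKA. In WT-AURKA c1 library D held 84.1 RPKM and the other 2 libraries 14.1 and 12.8 RPKM, close to the 12.7 and 14.3 RPKM of WT-AURKA c2. Without library D both WT-AURKA clones lay below Empty, by a mean log2 difference of -2.10 (limma adjusted p = 0.0021 for the clone with the larger p). With it the difference from Empty was -1.25 in WT-AURKA c1 (adjusted p = 0.135) and -2.10 in WT-AURKA c2 (adjusted p = 0.0269). In NLS-AURKA c2 library W held 104.6 RPKM, library H 56.5 and library X 38.4. The table has 1 AURKA row, so reads of the cDNA and of the gene are summed, and each clone is labelled with both a guide against AURKA and the cDNA, so a level above or below the controls does not check the labels.

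**Figure D2:**
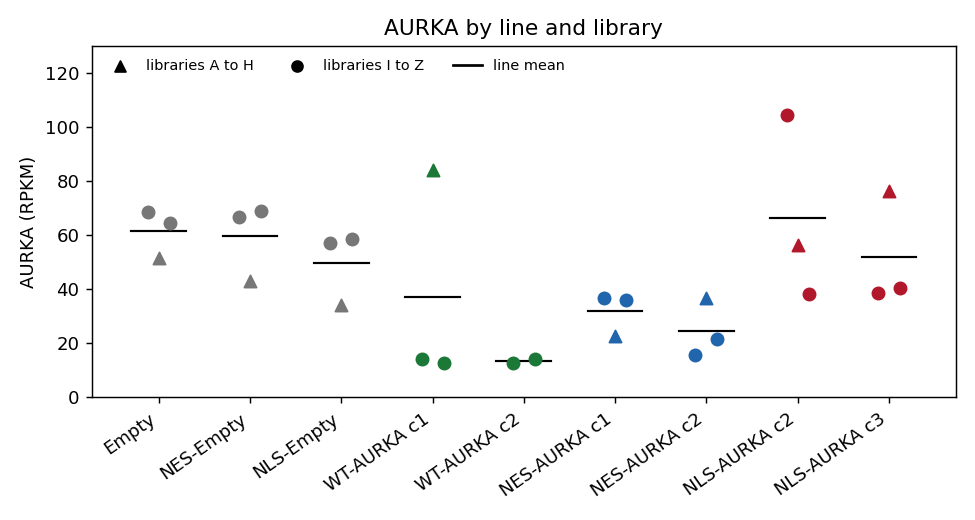
AURKA in RPKM (vertical axis, from 0) for each of the 9 lines, with triangles for libraries A to H, circles for I to Z and a black bar for the line mean. The WT-AURKA libraries lie between 12.7 and 14.3 RPKM except library D at 84.1 RPKM.

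The first comparison set the 6 AURKA lines against the 3 control lines, and asked what separates cells carrying AURKA cDNA from cells with the vector alone. SH3BGRL, a small thioredoxin-fold protein, rose from 0.208 ± 0.0879 RPKM (SD, n = 3 lines) to 21.4 ± 2.30 RPKM (n = 6), a log2 fold change of 4.19 (SE 0.11, limma adjusted p = 1.79e-08). SRGN, the proteoglycan core of secretory granules, rose from 7.69 ± 3.99 to 118 ± 52.9 RPKM (3.99, SE 0.49, adjusted p = 0.000806). HKDC1, a hexokinase-like enzyme, fell from 85.0 ± 2.83 to 5.18 ± 3.94 RPKM (-4.14, SE 0.48, adjusted p = 0.000624), and PSG9, a pregnancy-specific glycoprotein with near-identical relatives that the counting could split, from 25.9 ± 3.22 to 0.253 ± 0.117 RPKM (-4.04, SE 0.11, adjusted p = 1.79e-08). TMEM71 rose by 2.54 (SE 0.12, adjusted p = 3.00e-06) and MAL2, a protein of apical transport in epithelial cells, fell by 2.74 (SE 0.45, adjusted p = 0.00338). PAGE5, a cancer-testis gene, rose by 4.53 (SE 1.10, adjusted p = 0.0188) and KISS1, which encodes kisspeptin, by 3.79 (SE 0.89, adjusted p = 0.0167), yet neither passed once any 1 control line was left out (adjusted p 0.0723 to 0.0765 for PAGE5 and 0.0584 to 0.0743 for KISS1).

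Epithelial genes fell as a list. Of 27 measured, 13 fell and 0 rose over all genes tested, and 14 fell and 0 rose adjusted over the list alone, with a median log2 fold change of -0.78 (camera adjusted p = 2.22e-06, adjusted p = 0.434 with an estimated correlation). In the I to Z libraries the median was -0.41 (adjusted p = 0.000462, adjusted p = 0.295 with an estimated correlation). EPCAM, an epithelial adhesion molecule, fell from 12.3 ± 1.12 RPKM (n = 3 lines) to 2.42 ± 0.423 RPKM (n = 6; log2 fold change -1.96, SE 0.11, adjusted p = 8.75e-06), and the tight junction gene CLDN1 from 19.6 ± 1.76 to 4.67 ± 1.26 RPKM (-1.90, SE 0.19, adjusted p = 0.000314). CDH1, which encodes E-cadherin, fell from 3.64 ± 2.30 to 0.104 ± 0.0974 RPKM (-1.49, SE 0.19, adjusted p = 0.000871). The control mean of CDH1 rests largely on libraries E, C and G of the A to H set, at 3.14, 15.5 and 9.04 RPKM, while the I to Z means of Empty, NES-Empty and NLS-Empty were 0.492, 1.22 and 0.860 RPKM. Its log2 fold change in the I to Z libraries was -0.75 (adjusted p = 0.00227). The luminal breast markers, which share EPCAM and CDH1 with that list, had 4 of 14 lower and 0 higher, with the same counts adjusted over the list alone (camera adjusted p = 0.0287, adjusted p = 0.600 with an estimated correlation). They did not pass in the I to Z libraries (adjusted p = 0.291), without NLS-AURKA c2 (adjusted p = 0.0731) or without NLS-AURKA c3 (adjusted p = 0.0645). VIM, which encodes the mesenchymal intermediate filament vimentin, was at 317.7 ± 8.78 RPKM in control and 587 ± 246 RPKM in AURKA lines (0.78, SE 0.32, adjusted p = 0.114). Against matched control lines, where the spread between control lines and between constructs is left out, its adjusted p was 0.0303.

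Cholesterol synthesis genes rose as a list, with 11 of 24 higher and 0 lower, 15 and 0 adjusted over the list alone (median 0.46, camera adjusted p = 1.76e-06, adjusted p = 0.471 with an estimated correlation). MSMO1, a sterol methyl oxidase, rose from 20.3 ± 1.03 RPKM (n = 3 lines) to 53.5 ± 16.5 RPKM (n = 6; 1.18, SE 0.24, limma adjusted p = 0.00835). Interferon response genes had 11 of 40 higher and 3 lower, 14 and 4 adjusted over the list alone (median 0.29, camera adjusted p = 0.00376, adjusted p = 0.600 with an estimated correlation, and adjusted p = 0.0522 without the Empty line). BST2, which tethers budding virus particles, rose from 9.98 ± 4.41 to 68.6 ± 22.5 RPKM (2.73, SE 0.32, adjusted p = 0.000629), while IFI27 fell by 1.45 (SE 0.26, adjusted p = 0.00463). NF-kB and cytokine genes had 7 of 26 higher and 1 lower, 10 and 1 adjusted over the list alone (camera adjusted p = 0.00773, adjusted p = 0.600 with an estimated correlation). IL1B, a pyrogenic cytokine, rose by 1.71 (SE 0.22, adjusted p = 0.00103) and IL24 fell by 2.47 (SE 0.27, adjusted p = 0.000506).

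Antigen presentation genes were tested as 2 lists. Among 7 MHC class II genes 3 were higher and 0 lower, and 7 and 0 adjusted over the list alone, with a median log2 fold change of 1.2 (camera adjusted p = 0.00136, adjusted p = 0.600 with an estimated correlation). HLA-DRA was at 12.6 ± 8.48 RPKM (n = 6 lines) against 0.244 ± 0.117 RPKM (n = 3) and CD74, the invariant chain, at 24.6 ± 13.9 against 1.99 ± 0.854 RPKM, with limma adjusted p of 0.00596 and 0.00507. HLA genes are polymorphic and alike, so their values are uncertain. MHC class I presentation genes had 2 of 16 higher and 0 lower, with the same counts adjusted over the list alone (median 0.31, camera adjusted p = 0.00494, adjusted p = 0.600 with an estimated correlation). Of the markers of other cell types, 5 endothelial markers were tested and 3 were higher and 0 lower, 4 and 0 adjusted over the list alone (camera adjusted p = 0.00376, adjusted p = 0.434 with an estimated correlation). ROBO4, a receptor of endothelial cells, was at 7.56 ± 3.04 against 0.854 ± 0.0673 RPKM (2.14, SE 0.26, adjusted p = 0.000779). Of 3 leukocyte markers tested none was called (0 higher and 0 lower by either adjustment, camera adjusted p = 0.424).

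HIF target genes, the hypoxia-response list, did not move together, with 2 of 45 higher and 4 lower, 2 and 3 adjusted over the list alone (camera adjusted p = 0.901, median 0.045, mean -0.003, test direction higher). HIF1A, the oxygen-regulated transcription factor, fell from 117.7 ± 11.1 RPKM (n = 3 lines) to 71.9 ± 12 RPKM (n = 6; -0.70, SE 0.16, adjusted p = 0.0127) and VEGFA, an angiogenic growth factor, from 22.7 ± 1.59 to 10.9 ± 2.49 RPKM (-1.03, SE 0.19, adjusted p = 0.00512), but within the I to Z libraries their adjusted p were 0.0519 and 0.0680. The HIF1A call was also lost without NES-Empty (adjusted p = 0.0731) or NLS-Empty (adjusted p = 0.0651). The glycolytic gene PGK1 rose by 0.87 (SE 0.12, adjusted p = 0.00130). Of 40 mitosis genes 7 were higher and 0 lower, with the same counts adjusted over the list alone (median 0.08, camera adjusted p = 0.0781; I to Z, median -0.01, adjusted p = 0.732). Libraries D and A, both of AURKA lines, stood apart in these genes, with median shifts against the other lines of 1.02 and 1.01 on the log2 scale. FOXM1, a transcription factor of the G2/M programme, rose from 11.3 ± 0.481 to 24.5 ± 5.19 RPKM (0.98, SE 0.17, adjusted p = 0.00396). AURKB and TPX2, a partner that activates AURKA on the spindle, differed by 0.02 (adjusted p = 0.911) and 0.11 (adjusted p = 0.473). Of 20 Aurora A partners and activators 1 was higher and 1 lower, with the same counts adjusted over the list alone (camera adjusted p = 0.992, median 0.0027, mean -0.07, test direction lower). Of 32 breast cancer metastasis genes 6 were higher and 2 lower, with the same counts adjusted over the list alone (camera adjusted p = 0.228), among them TNC, an extracellular matrix glycoprotein, which rose by 1.47 (SE 0.18, adjusted p = 0.00083).

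Over all genes, 2423 of 12589 were called between AURKA and control lines, 1114 higher and 1309 lower. The values of the 9 lines did not overlap between arms for 96.12% of them. These genes were selected for a difference between the arms, so that share is no further support. Within the I to Z libraries 2177 were called (928 higher and 1249 lower), of which 1763 were also called in the pooled fit. Without Empty, NES-Empty or NLS-Empty, 1032, 934 and 915 genes were called. The 6 AURKA clones also differed from the controls in guide, passage and clonal derivation, so this contrast is not one of AURKA cDNA alone.

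Each construct was also compared with the control line that carried the same signal, to ask which genes moved in both clones. In both WT-AURKA clones against Empty, 214 genes were higher and 116 lower. PAGE5 was at 76.5 and 80.8 RPKM in the clones and listed at 0 in Empty, and CCBE1, a secreted factor of lymphatic growth, was at 0.00339 and 0.00546 RPKM against 8.18 RPKM, with log2 differences of -3.18 (SE 0.14) and -3.17 (SE 0.16). In both NES-AURKA clones against NES-Empty, 85 genes were higher and 129 lower. EMB, an immunoglobulin-family adhesion protein, was at 9.94 and 8.47 RPKM against 0.404 RPKM, with log2 differences of 2.97 and 2.76 (SE 0.17 each). In both NLS-AURKA clones against NLS-Empty, 300 genes were higher and 268 lower. ADAMTS1, a secreted protease, was at 30.4 and 23.6 RPKM against 0.398 RPKM (4.42 and 4.14, SE 0.24 each), KISS1 at 303 and 259 RPKM against 5.77 RPKM (5.66 and 5.51, SE 0.85 each), and the hair keratin KRT81 at 3.54 and 2.49 RPKM against 357 RPKM (-6.33 and -6.66, SE 0.51 each). KRT81 has a near-identical relative, KRT86, so its value is uncertain. In the I to Z libraries these counts were 279 and 184 for WT-AURKA, 131 and 154 for NES-AURKA, and 297 and 303 for NLS-AURKA.

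The sets overlapped. WT-AURKA and NES-AURKA shared 62 of the higher and 71 of the lower genes, where independent lists would share 1.45 and 1.19. WT-AURKA and NLS-AURKA shared 74 and 61 (5.1 and 2.47 for independent lists), and NES-AURKA and NLS-AURKA shared 34 and 73 (2.03 and 2.75). These comparisons have no control library in common, but passage, clonal derivation and a guide against AURKA set all AURKA clones apart from all controls. Such shared differences could make the lists overlap, so the values for independent lists are a reference and not a test of AURKA cDNA. In all 3 constructs 30 genes were higher and 48 lower, against 0.0344 and 0.0253 for independent lists. The higher genes included SH3BGRL, SRGN, BST2, HLA-DRA and TNC, and the lower ones HKDC1, EPCAM, MAL2, PSG9 and ABCG2, a drug efflux pump named after its values were seen. WT-AURKA counts rest on few libraries of c2, and without library Q or R they were 198 and 199 in place of 330.

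NLS-AURKA against NES-AURKA set the nuclear localization signal against the nuclear export signal. Where the protein lay was not measured here, and AURKA RNA was itself higher in NLS-AURKA. ADAMTS1 rose from 0.631 ± 0.146 RPKM (SD, n = 2 lines) in NES-AURKA to 27.0 ± 4.78 RPKM (n = 2) in NLS-AURKA, a log2 fold change of 4.08 (SE 0.13, limma adjusted p = 4.57e-07). CXCR4, the chemokine receptor for CXCL12, rose from 0.216 ± 0.270 to 18.5 ± 6.06 RPKM (3.93, SE 0.19, adjusted p = 5.04e-06), MMP1, interstitial collagenase, from 85.2 ± 1.19 to 752 ± 126 RPKM (3.35, SE 0.34, adjusted p = 0.000238), and KISS1 from 27.4 ± 21.6 to 281 ± 31.6 RPKM (3.53, SE 0.46, adjusted p = 0.000713). KRT81 fell from 525 ± 125 to 3.01 ± 0.748 RPKM (-6.91, SE 0.26, adjusted p = 1.41e-06). LCP1, an actin-bundling protein, fell from 53.1 ± 28.2 to 3.23 ± 0.453 RPKM (-3.58, SE 0.44, adjusted p = 0.000518), TNS4, a focal adhesion protein, by 3.65 (SE 0.15, adjusted p = 2.19e-06) and S100P, a calcium-binding protein, by 3.57 (SE 0.21, adjusted p = 1.63e-05).

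**Figure D3:**
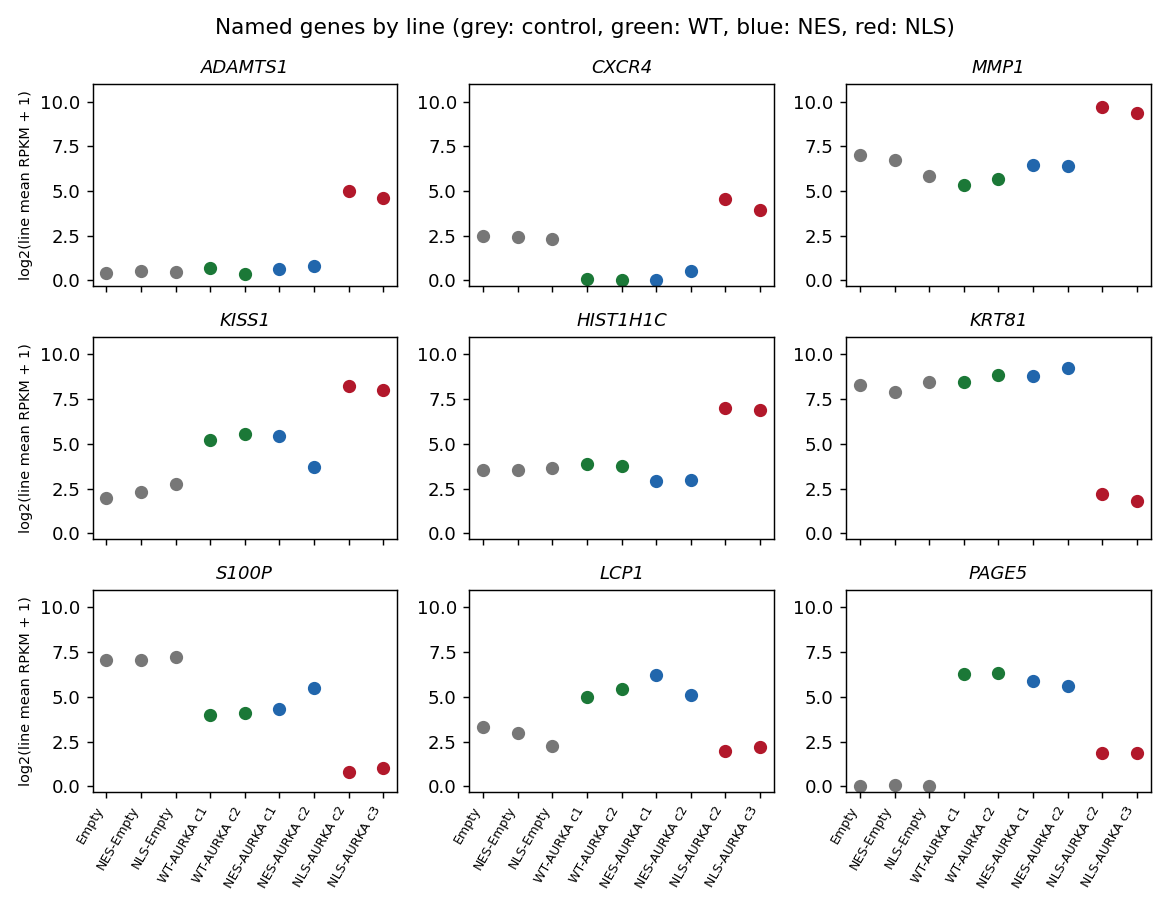
Mean level of 9 named genes in each of the 9 lines, as log2(mean RPKM + 1) on the vertical axis, one point per line (grey control, green WT-AURKA, blue NES-AURKA, red NLS-AURKA). ADAMTS1, CXCR4, MMP1, KISS1 and HIST1H1C are highest in both NLS-AURKA clones and KRT81 and S100P lowest, and CXCR4 was at 4.26 ± 0.315 RPKM in the control lines, 0.0281 ± 0.0170 in WT-AURKA and 0.216 ± 0.270 in NES-AURKA, and PAGE5 at 0.0106 ± 0.0183 RPKM in the control lines.

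Replication-dependent histone genes rose as a list in NLS-AURKA, with 10 of 15 higher and 0 lower, with the same counts adjusted over the list alone (median 0.90, camera adjusted p = 4.76e-05, adjusted p = 0.598 with an estimated correlation). The linker histone gene HIST1H1C rose from 6.84 ± 0.157 RPKM (n = 2 lines) to 122 ± 8.57 RPKM (n = 2; 3.62, SE 0.09, adjusted p = 1.88e-07), and HIST1H2AC, a core histone gene, from 6.26 ± 2.09 to 65.1 ± 1.45 RPKM (3.13, SE 0.16, adjusted p = 7.00e-06). Most transcripts of this class lack poly(A) tails, and the letter sets also differed in MALAT1 and NEAT1 levels. In the A to H libraries 10 of the 15 were higher in NLS-AURKA (median difference 0.48), and in the I to Z libraries 14 of 15 (1.11).

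TGF-beta target genes fell as a list, with 9 of 23 lower and 1 higher, 9 and 3 adjusted over the list alone (median -0.25, camera adjusted p = 0.0227, adjusted p = 0.598 with an estimated correlation). Without libraries D and A the camera adjusted p was 0.0565. ID1, an inhibitor of basic helix-loop-helix factors, fell from 89.1 ± 3.86 RPKM (n = 2 lines) to 27.7 ± 2.62 RPKM (n = 2; -1.96, SE 0.14, adjusted p = 4.43e-05), and TGFBI, a secreted adhesion protein, from 12.8 ± 4.21 to 2.06 ± 0.275 RPKM (-2.10, SE 0.19, adjusted p = 0.000162). Lysosome genes fell too, with 10 of 24 lower and 2 higher, 11 and 3 adjusted over the list alone (median -0.27, camera adjusted p = 0.0118, adjusted p = 0.894 with an estimated correlation). The cathepsin genes CTSB and CTSZ fell by 1.54 (SE 0.19, adjusted p = 0.000488) and 1.38 (SE 0.12, adjusted p = 0.000104).

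Members of other lists moved in both directions. Of 45 HIF target genes 5 were higher and 10 lower, with the same counts adjusted over the list alone (camera adjusted p = 0.204). The list was lower in the I to Z libraries (adjusted p = 0.0461, adjusted p = 0.673 with an estimated correlation) and without NES-AURKA c1 (adjusted p = 0.0458). LOX, which crosslinks collagen, rose by 1.82 (SE 0.14, adjusted p = 6.74e-05), while BHLHE40 fell by 1.70 (SE 0.17, adjusted p = 0.000234). HIF1A was at 57.1 ± 2.20 RPKM in NLS-AURKA and 81.3 ± 3.03 RPKM in NES-AURKA (n = 2 lines each; -0.53, SE 0.11, adjusted p = 0.00683), and its adjusted p was 0.0588 without NLS-AURKA c2. VIM rose from 515 ± 227 to 864 ± 49.4 RPKM (0.83, SE 0.25, adjusted p = 0.0327), a call lost without either NLS-AURKA clone (adjusted p = 0.152 without c2 and 0.107 without c3) or without any 1 of the control or WT-AURKA lines (0.0526 to 0.0540). Of 32 breast cancer metastasis genes 9 were higher and 13 lower, 11 and 13 adjusted over the list alone (camera adjusted p = 0.588), and the list holds ADAMTS1, CXCR4, MMP1 and KRT81. Mitosis genes had 2 of 40 higher and 4 lower, with the same counts adjusted over the list alone (camera adjusted p = 0.975; I to Z, higher, adjusted p = 0.0237, adjusted p = 0.673 with an estimated correlation), and Aurora A partners 3 of 20 higher and 3 lower, with the same counts adjusted over the list alone (camera adjusted p = 0.840, median 0.03, mean 0.016, test direction lower). TPX2 and AURKB differed by 0.18 (adjusted p = 0.242) and 0.20 (adjusted p = 0.367) in the pooled fit and by 0.40 (adjusted p = 0.0122) and 0.41 (adjusted p = 0.00909) in the I to Z libraries. CDH1 and VEGFA did not pass (adjusted p = 0.624 and 0.486), and VEGFA passed in the I to Z libraries (-0.81, adjusted p = 0.0251). Without NES-AURKA c2 the adjusted p of TPX2, AURKB and VEGFA were 0.0384, 0.00342 and 0.0333.

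In all, 4180 genes were called between NLS-AURKA and NES-AURKA, 2408 higher and 1772 lower, and 242 and 220 of them by at least 1 on the log2 scale. Within the I to Z libraries 4716 were called (2468 higher and 2248 lower), of which 3639 were called in both fits. A further requirement of a call in each of the 4 pairings of clones, at the level of libraries, left 205 genes (118 higher and 87 lower; 293 in the I to Z libraries). With 2 lines per construct that may not be independent isolates, and with another guide and cDNA label in NLS-AURKA, these p-values measure the spread between the lines as deposited. AURKA level, guide and cDNA label cannot be separated from the signal in this contrast. The count was 2250 without NLS-AURKA c2 and 2510 without NLS-AURKA c3.

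NLS-AURKA against WT-AURKA set the nuclear signal against AURKA without an added signal. Guide, cDNA label and AURKA level differed here as well and cannot be separated from the signal. Letter set was also unbalanced in the pooled fit, since WT-AURKA c2 has I to Z libraries alone. ADAMTS1 rose from 0.440 ± 0.213 RPKM (SD, n = 2 lines) to 27.0 ± 4.78 RPKM (n = 2; 4.26, SE 0.13, limma adjusted p = 4.89e-07), CXCR4 from 0.0281 ± 0.0170 to 18.5 ± 6.06 RPKM (4.15, SE 0.19, adjusted p = 3.33e-06) and MMP1 from 44.1 ± 6.83 to 752 ± 126 RPKM (4.07, SE 0.34, adjusted p = 8.91e-05). CKB, the brain-type creatine kinase, rose by 2.87 (SE 0.34, adjusted p = 0.000372) and PTK7, a Wnt pathway pseudokinase receptor, by 2.44 (SE 0.30, adjusted p = 0.000501). SERPINB2, plasminogen activator inhibitor 2, fell from 18.4 ± 0.112 to 0.637 ± 0.341 RPKM (-3.57, SE 0.38, adjusted p = 0.000245), S100A4, a calcium-binding protein linked to cell motility, from 145.9 ± 1.82 to 13.2 ± 2.41 RPKM (-3.36, SE 0.42, adjusted p = 0.000495), and SYK, a tyrosine kinase best known in immune cells, from 10.9 ± 1.57 to 0.206 ± 0.194 RPKM (-3.32, SE 0.26, adjusted p = 7.50e-05). In the control line Empty SERPINB2 was at 0.265 RPKM. Its low level in NLS-AURKA is therefore no fall below that control, and WT-AURKA was far above it.

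The histone genes rose here as well, with 10 of 15 higher and 0 lower, with the same counts adjusted over the list alone (median 0.67, camera adjusted p = 2.82e-05, adjusted p = 0.959 with an estimated correlation), HIST1H1C by 2.78 (SE 0.09, adjusted p = 6.69e-07). Lysosome genes fell, with 14 of 24 lower and 1 higher, 15 and 1 adjusted over the list alone (median -0.46, camera adjusted p = 8.50e-05, adjusted p = 0.959 with an estimated correlation). CTSB fell from 65.7 ± 4.24 RPKM (n = 2 lines) to 15.6 ± 0.702 RPKM (n = 2; -2.0, SE 0.19, adjusted p = 0.000126), CTSD, the aspartic cathepsin, by 1.54 (SE 0.28, adjusted p = 0.00307) and LAMP2, a lysosomal membrane protein, by 1.10 (SE 0.11, adjusted p = 0.000161). VIM rose from 382 ± 1.10 to 864 ± 49.4 RPKM (1.16, SE 0.25, adjusted p = 0.00705; adjusted p = 0.055 without NLS-AURKA c2), and HIF1A was at 57.1 ± 2.20 against 77.4 ± 5.38 RPKM (-0.46, SE 0.11, adjusted p = 0.0119), a call lost without WT-AURKA c1 (adjusted p = 0.0584) or NLS-AURKA c2 (adjusted p = 0.0882). VEGFA and CDH1 did not pass (adjusted p = 0.404 and 0.895).

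**Figure D4:**
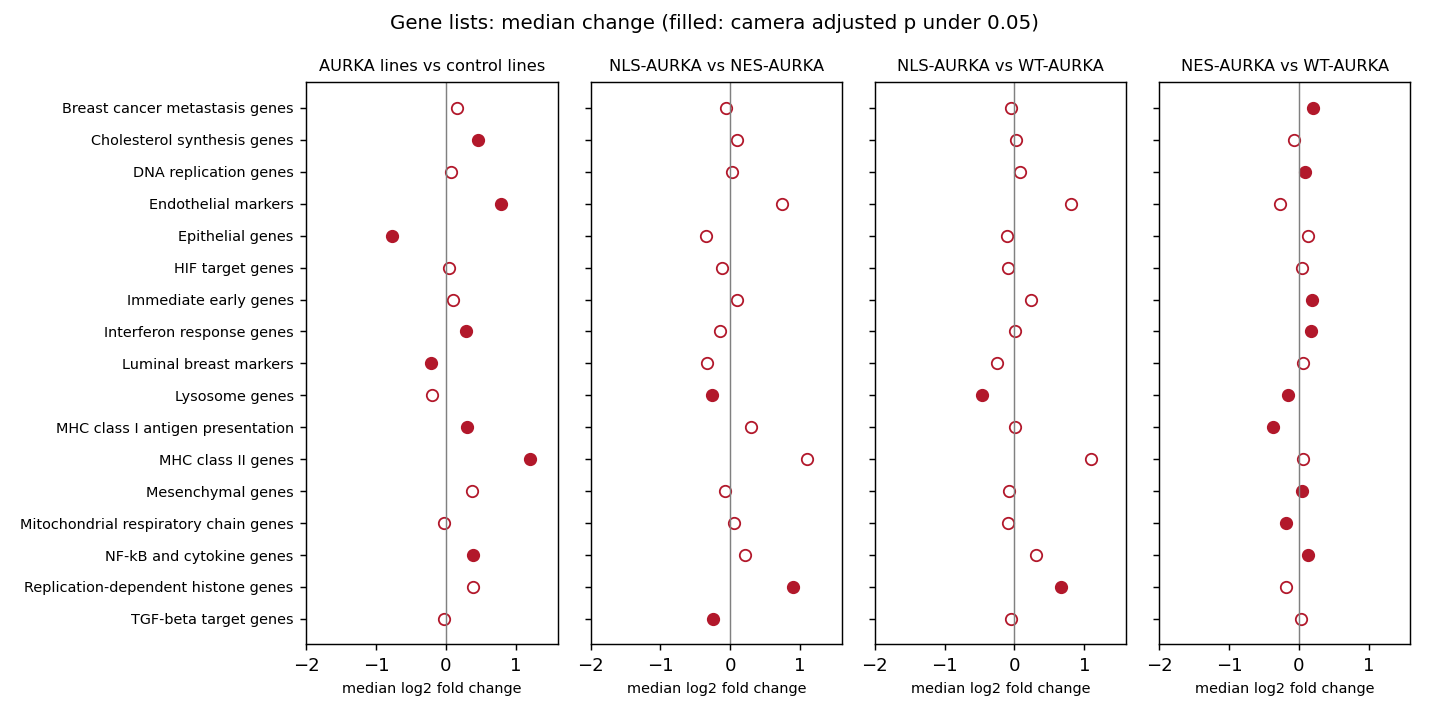
Median log2 fold change of each gene list in the 4 contrasts between groups of lines, for lists called in any contrast and the HIF target genes, filled where the camera adjusted p is under 0.05 at the preset correlation. No list call in the figure held with an estimated correlation.

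HIF target genes had 8 of 45 higher and 9 lower, with the same counts adjusted over the list alone (camera adjusted p = 0.762), LOX being higher by 1.70 (SE 0.14, adjusted p = 8.71e-05) and the hexokinase gene HK2 by 0.88 (SE 0.15, adjusted p = 0.00229). Breast cancer metastasis genes had 11 of 32 higher and 8 lower, 13 and 11 adjusted over the list alone (camera adjusted p = 0.762, median -0.05, mean 0.17, test direction higher). Aurora A partners had 3 of 20 higher and 6 lower, with the same counts adjusted over the list alone (camera adjusted p = 0.762), among them CDC25B, a phosphatase that activates CDK1, which fell by 1.0 (SE 0.09, adjusted p = 1.0e-04), and BORA, an activator of AURKA, which fell by 0.94 (SE 0.11, adjusted p = 0.000324). Mitosis genes had 2 of 40 higher and 8 lower, with the same counts adjusted over the list alone (median -0.03, mean 0.018, camera adjusted p = 0.849, test direction lower), while within the I to Z libraries their median was 0.35 and the list was higher (adjusted p = 0.000196, adjusted p = 0.791 with an estimated correlation). TPX2 and AURKB likewise differed by 0.22 (adjusted p = 0.144) and 0.17 (adjusted p = 0.411) in the pooled fit and by 0.60 (adjusted p = 0.00176) and 0.60 (adjusted p = 0.0015) in the I to Z libraries. TPX2 also passed without NES-AURKA c1 (adjusted p = 0.0477) or NES-AURKA c2 (adjusted p = 0.0480). Libraries D of WT-AURKA c1 and A of NES-AURKA c2 stood apart in these genes. TPX2 was at 99.2 and 108.9 RPKM in D and A, against 51.6 to 66.6 RPKM in the other A to H libraries, and AURKB at 18.1 and 22.8 RPKM against 7.44 to 12.2 RPKM. With both left out, TPX2 and AURKB differed by 0.25 (adjusted p = 0.0758) and 0.18 (adjusted p = 0.364) between NLS-AURKA and WT-AURKA. That fit is unbalanced, since WT-AURKA keeps I to Z libraries alone and NLS-AURKA keeps H and B of the A to H set. TPX2 was at 60.5 and 66.6 RPKM in H and B, against 120.4 to 154.3 RPKM in the I to Z libraries of NLS-AURKA. The smaller differences therefore cannot separate letter set from construct.

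Between NLS-AURKA and WT-AURKA 4547 genes were called, 2360 higher and 2187 lower. Within the I to Z libraries 4846 were called (2567 higher and 2279 lower), with 3765 called in both fits. In each of the 4 pairings of clones 275 genes were called (123 higher and 152 lower), and 451 in the I to Z libraries. Leaving out library Q or R of WT-AURKA c2 lowered the 275 to 165 and 152, and the 4547 were 2643 without WT-AURKA c2 and 2509 without NLS-AURKA c2.

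NES-AURKA against WT-AURKA compared AURKA with an export signal to AURKA without one, the contrast in which both constructs carry the same guide and cDNA labels. Letter set was not balanced in the pooled fit, since WT-AURKA c2 has I to Z libraries alone. With letter-set-adjusted line values, chosen after seeing the data, 613 genes were called, and 491 of these were called in both fits. APCS, serum amyloid P component, was at 5.45 ± 1.27 RPKM (SD, n = 2 lines) in NES-AURKA and was listed at 0 in WT-AURKA (limma adjusted p = 3.23e-05). SRPX, a sushi-repeat protein, rose from 4.54 ± 0.0105 to 16.7 ± 4.74 RPKM (1.63, SE 0.17, adjusted p = 0.00542) and EGR1, an immediate early transcription factor, from 15.3 ± 1.12 to 60.3 ± 31.5 RPKM (1.48, SE 0.23, adjusted p = 0.0133). SERINC2 fell from 53.4 ± 0.980 to 17.2 ± 6.70 RPKM (-1.63, SE 0.21, adjusted p = 0.00684), SEMA7A, a membrane-anchored semaphorin, from 33.2 ± 3.90 to 15.2 ± 2.38 RPKM (-1.13, SE 0.14, adjusted p = 0.00646) and OPN3, an opsin, by 1.56 (SE 0.22, adjusted p = 0.0102). MAGEA3 and MAGEA6, cancer-testis genes with near-identical sequences and so uncertain values, fell by 2.01 (SE 0.29, adjusted p = 0.0102) and 2.25 (SE 0.25, adjusted p = 0.00543). Without WT-AURKA c2, when 20 genes were called in all, APCS and MAGEA6 still passed. The others did not (SRPX 0.0567, EGR1 0.105, SERINC2 0.0907, SEMA7A 0.0872, OPN3 0.0997 and MAGEA3 0.0983 as adjusted p), and EGR1 was also lost without WT-AURKA c1 (adjusted p = 0.0517).

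Interferon response genes were higher as a list in NES-AURKA, with 4 of 40 higher and 0 lower, 7 and 1 adjusted over the list alone (median 0.18, camera adjusted p = 0.000650, adjusted p = 0.659 with an estimated correlation, and adjusted p = 0.217 without NES-AURKA c1). OASL rose from 3.44 ± 0.0166 RPKM (n = 2 lines) to 10.6 ± 2.01 RPKM (n = 2; 1.30, SE 0.24, adjusted p = 0.0223) and DDX58, the RNA sensor RIG-I, by 0.97 (SE 0.14, adjusted p = 0.0102). Breast cancer metastasis genes had 3 of 32 higher and 0 lower, 5 and 2 adjusted over the list alone (camera adjusted p = 0.00256, adjusted p = 0.231 with an estimated correlation). These were L1CAM, an adhesion molecule, TNC, and HBEGF, a ligand of the EGF receptor, with log2 fold changes of 0.88, 0.70 and 0.63 (SE 0.13, 0.12 and 0.10). Without WT-AURKA c2 the adjusted p of OASL, DDX58, L1CAM, TNC and HBEGF were 0.164, 0.105, 0.111, 0.12 and 0.116. OASL was also lost without WT-AURKA c1 (0.0683) or either NLS-AURKA clone (0.0531 and 0.0532), and TNC without WT-AURKA c1 (0.0603).

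Immediate early genes had 2 of 25 higher and 0 lower, with the same counts adjusted over the list alone (camera adjusted p = 0.00488, adjusted p = 0.659 with an estimated correlation), and were lost without WT-AURKA c1 (adjusted p = 0.107) or NES-AURKA c1 (adjusted p = 0.0721). DNA replication genes had 1 of 41 higher and 0 lower, with the same counts adjusted over the list alone (median 0.09, camera adjusted p = 0.00488, adjusted p = 0.659 with an estimated correlation, and adjusted p = 0.0769 without NES-AURKA c2). In the I to Z libraries their median was 0.29 (adjusted p = 3.42e-07, adjusted p = 0.633 with an estimated correlation). NF-kB and cytokine genes had 3 of 26 higher and 0 lower, 6 and 1 adjusted over the list alone (camera adjusted p = 0.0211, adjusted p = 0.659 with an estimated correlation). They did not pass in the I to Z libraries (adjusted p = 0.577), without WT-AURKA c1 (0.107) or without NES-AURKA c1 (0.362). Mesenchymal genes had 2 of 19 higher and 0 lower, 5 and 2 adjusted over the list alone (camera adjusted p = 0.0497, adjusted p = 0.659 with an estimated correlation; I to Z, 0.176).

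Mitochondrial respiratory chain genes were lower as a list, with 3 of 44 lower and 0 higher, with the same counts adjusted over the list alone (median -0.18, camera adjusted p = 0.00458, adjusted p = 0.659 with an estimated correlation). In the I to Z libraries their median was 0.01 (adjusted p = 0.836), and the call was lost without WT-AURKA c2 (adjusted p = 0.0948) or NES-AURKA c1 (adjusted p = 0.212). MHC class I presentation genes had 0 of 16 called over all genes, and 0 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.0497, adjusted p = 0.805 with an estimated correlation). Lysosome genes had 1 of 24 higher and 1 lower, with the same counts adjusted over the list alone (median -0.16, camera adjusted p = 0.0497, adjusted p = 0.659 with an estimated correlation). The mesenchymal, MHC class I and lysosome calls were each lost without WT-AURKA c2 (adjusted p = 0.103, 0.103 and 0.395), NES-AURKA c2 (0.204, 0.922 and 0.328), NLS-AURKA c2 (0.0555 each) or NLS-AURKA c3 (0.0555 each), and the mesenchymal and MHC class I calls also without WT-AURKA c1 (0.0659 and 0.0603).

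HIF target genes had 3 of 45 higher and 1 lower, 4 and 1 adjusted over the list alone (camera adjusted p = 0.142). The list was higher in the I to Z libraries (adjusted p = 0.00378, adjusted p = 0.633 with an estimated correlation) and without NES-AURKA c1 (adjusted p = 0.0206). Mitosis genes and Aurora A partners each had 0 higher and 1 lower, with the same counts adjusted over the list alone (camera adjusted p = 0.735 and 0.904). Within the I to Z libraries the mitosis list was higher, with a median of 0.10 (adjusted p = 0.0227, adjusted p = 0.634 with an estimated correlation). HIF1A, VEGFA, VIM, CDH1, AURKB and TPX2 did not pass (adjusted p = 0.761, 0.954, 0.462, 0.804, 0.948 and 0.860), and VIM passed without NES-AURKA c1 (0.82, adjusted p = 0.00281).

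Between NES-AURKA and WT-AURKA 613 genes were called, 197 higher and 416 lower, so 32.1% were higher. With median-of-ratios scaling, chosen after seeing the data, 462 were called (243 higher and 219 lower, 52.6% higher), and 413 of these were called in both fits. Within the I to Z libraries 572 were called (256 higher and 316 lower), of which 318 were also called in the pooled fit. The count was 20 without WT-AURKA c2, 2433 without NES-AURKA c1 and 2058 without NES-AURKA c2. Without Empty, NES-Empty or NLS-Empty it was 251, 212 and 224, and 235 without either NLS-AURKA clone. These lines are outside the contrast, so leaving them out changed the shared estimate of spread and no fold change. Leaving out a NES-AURKA clone takes the difference between the NES-AURKA clones out of that estimate, so the larger counts are no sign of robustness. In each of the 4 pairings of clones 12 genes were called (4 higher and 8 lower), 34 in the I to Z libraries, and 5 and 7 without library Q or R. The 4 higher ones were SRPX, AKR1C3, an aldo-keto reductase, the protocadherin gene PCDH1 and RP5-1086K13.3, the last 3 named after their values were seen.

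Clones of a construct and control lines were compared to show how far lines differ without a change of construct. The 2 NES-AURKA clones differed in 136 genes, 30 higher and 106 lower in c2, and in 228 in the I to Z libraries. CALHM2, which encodes a calcium homeostasis modulator, was at 5.37 RPKM in c2 and 0.226 RPKM in c1 (log2 difference 2.31, SE 0.19, limma adjusted p = 3.34e-07, n = 3 libraries each), SSX1, a cancer-testis gene, at 7.42 and 0.925 RPKM (2.01, SE 0.32, adjusted p = 0.000916), and COX7B2 at 0.0781 and 8.36 RPKM (-3.07, SE 0.49, adjusted p = 0.000924). In contrast, limma called 0 genes between the 2 WT-AURKA clones (57 at an unadjusted p under 0.05) and 0 between the 2 NLS-AURKA clones (114 unadjusted), and 11 between the latter in the I to Z libraries. The spread in the fit to all libraries includes the difference between letter sets, which limits what few calls can show. With a letter-set term 164 and 486 passed unadjusted, and 0 were called in either pair. NES-Empty and Empty differed in 2 genes (1 without library E, I or L), of which PGM5, a phosphoglucomutase-related protein, was at 0.299 and 5.60 RPKM (-2.35, SE 0.24, adjusted p = 3.72e-05). The other was IGFL1, named after its values were seen, at 2.37 and 0.497 RPKM. Between NLS-Empty and Empty limma called 0 genes (144 unadjusted; 1 without library E). In the I to Z libraries these counts were 5 and 7. The median distance between I to Z libraries, as the root mean square difference of log2(RPKM + 1), was 0.163 between the WT-AURKA clones, 0.175 within a line, 0.184 between control lines, 0.352 between the NLS-AURKA clones, and 0.403 between the NES-AURKA clones. Between constructs it was 0.361 for WT-AURKA and NES-AURKA (0.339 to 0.394), no more than between the NES-AURKA clones (0.394 to 0.424), and 0.579 and 0.620 for NLS-AURKA against WT-AURKA and NES-AURKA. Libraries W and X of NLS-AURKA c2 were 0.495 apart. Among the A to H libraries the NES-AURKA clones were 0.718 apart, farther than any 2 clones of different constructs (0.483 to 0.661), the NLS-AURKA clones 0.169 apart and control lines 0.166 to 0.225.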

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

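All tests of the AURKA value in library D were chosen after that value had been seen. Among 59 groups of 4 to 10 libraries or lines in which an extreme value was sought, 6 held one, and chance alone marks about 5% of such groups. Library D of WT-AURKA c1 held 84.1 RPKM of AURKA, where the nearest of the other WT-AURKA libraries held 14.3 RPKM. CA9, an enzyme of acid-base balance and a HIF target, was at 1.47 RPKM in library C of NES-Empty, with the next control library at 0.488 RPKM. CDH1 was at 0.616 RPKM in library F of NES-AURKA c1, with the next NES-AURKA library at 0.162 RPKM. Over the AURKA lines, CDH1 had its highest mean in NES-AURKA c1, 0.294 RPKM, with the next line at 0.101 RPKM, while its I to Z means in NES-AURKA c1 and c2 were 0.1335 and 0.124 RPKM. CDR1-AS, an antisense RNA whose value is uncertain because no strand setting is given, was at 25.8 RPKM in NES-AURKA c1 and at most 9.78 RPKM in the other AURKA lines, but that value rests on library F, since in the I to Z libraries it was 7.76 RPKM there and 8.64 RPKM in WT-AURKA c1. UCA1, a long non-coding RNA, was at 26.5 RPKM in NES-AURKA c2 and at most 8.13 RPKM in the other AURKA lines, which rests on library A, since in the I to Z libraries it was 3.43 RPKM there and 7.30 RPKM in NES-AURKA c1.

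The effect of a construct against its matched control line was compared between constructs in a limma interaction test with 3 residual degrees of freedom. These come from the 3 pairs of clones alone, since each control is 1 line, so the spread between control lines is not in the test, and the counts would be too high if clones of a pair were 1 isolate. Between NLS-AURKA and NES-AURKA it differed for 174 genes (109 higher and 65 lower), and between NLS-AURKA and WT-AURKA for 282 (139 and 143). Between NES-AURKA and WT-AURKA limma called 0 genes (675 at an unadjusted p under 0.05). AURKA itself did not pass in any of these 3 tests, with adjusted p of 0.250, 0.0997 and 0.980.

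An exchange of library D with that of another line would reverse the differences between their lines, but of the genes called between them in the I to Z libraries 91.7% kept their direction for library A (121 of 132), at least 82.96% for the NLS-AURKA libraries and at least 95.1% for the control libraries, which argues against these exchanges. For library F of NES-AURKA c1 it was 70.5%, which does not decide, although the other libraries of that line held 37.0 and 36.2 RPKM of AURKA and those of NES-AURKA c2 15.5 and 21.5 RPKM, all below the level in D. A shift of the AURKA row between letter sets would raise the A to H library in every line, but in 5 of 8 lines it lay below the I to Z mean, with ratios of 0.589 to 0.790, against 6.24 in WT-AURKA c1, 1.98 in NES-AURKA c2 and 1.94 in NLS-AURKA c3. More dividing cells would raise the mitosis genes alike, whose shift against the other lines had a median of 1.02 on the log2 scale in D (SD 0.28) and 1.01 in A, where AURKA shifted by 2.91 (above every mitosis gene) and 1.32, so it is argued against as the whole cause in D and stays open as a part. A higher level of the cDNA in library D may account for the rest, as a hypothesis, but with 1 row for AURKA, cDNA and gene cannot be told apart.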

How the results depend on the processing

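Median-of-ratios scaling, letter-set-adjusted line values, leaving out libraries D and A, the A to H libraries alone, and the I to Z libraries alone for single-line comparisons were chosen after the results had been seen. The cause of the changes given here was not tested, except that a stricter filter tests fewer genes and leaving out libraries removes samples. By design, leaving out a line outside a contrast between constructs changes no fold change of that contrast, only the shared estimate of spread. Leaving out 1 of the 2 clones of a construct takes the difference between them out of that estimate in the contrasts between constructs. Of the counts of called genes, 97 values under other settings stayed within 1.5 times the main count and 43 did not; with a line or library left out, 100 did and 25 did not. Of the list tests, 96 kept direction and side of the threshold under other settings, 51 lost the call, 3 gained one, 3 reversed and 3 changed sign without a call; with a line left out, 206 kept them, 25 lost the call, 2 gained one and 1 changed sign without a call. Of the named genes, 2187 kept them under other settings, 218 lost the call, 11 gained one, 3 reversed and 27 changed sign without a call. With a line or library left out, 1906 kept them, 241 lost the call, 8 gained one, 0 reversed and 20 changed sign without a call. The 3 reversed genes were AURKA (-0.35), BHLHE40 (0.20) and MKI67 (-0.88) in NLS-AURKA against WT-AURKA in the A to H libraries, without a call there (adjusted p = 0.623, 0.897 and 0.396). The reversed lists, all in NES-AURKA against WT-AURKA, were the mitochondrial respiratory chain genes, lower in all libraries and on the higher side in the I to Z libraries (adjusted p = 0.836), and in the A to H libraries the DNA replication genes (lower, adjusted p = 0.0882) and lysosome genes (higher, 0.220). With fry, 12 of the list calls were lost, and no list call held with an estimated correlation. Genes near 1 RPKM, the floor of the filter, are limited most by depth. No paired analysis was possible because the labels share no replicate numbers between lines.

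The A to H libraries alone, where WT-AURKA is library D, gave 1455 genes between AURKA and control lines, 986 between NLS-AURKA and NES-AURKA, 387 between NLS-AURKA and WT-AURKA and 0 between NES-AURKA and WT-AURKA. With the stricter filter of 10 RPKM, 1099 genes were called between AURKA and control lines, 1996 between NLS-AURKA and NES-AURKA, 2232 between NLS-AURKA and WT-AURKA and 385 between NES-AURKA and WT-AURKA. In the clone pairings in that order the stricter filter gave 92, 122 and 3, against matched controls 147 (WT-AURKA), 96 (NES-AURKA) and 238 (NLS-AURKA), between the NES-AURKA clones 36 and between NES-Empty and Empty 0. Matched control lines, a fit that leaves out the spread between control lines and between constructs, gave 4043 for AURKA against control lines. The line as a random block gave 1273 for NES-AURKA against WT-AURKA. A pseudocount of 0.1 gave 417, 522 and 21 in the clone pairings, 609, 441 and 1024 against matched controls, and 274 between the NES-AURKA clones. With no fold threshold the numbers were 829, 926 and 30, then 930, 737 and 1685, and 571. The I to Z libraries alone gave 451 for NLS-AURKA against WT-AURKA and 34 for NES-AURKA against WT-AURKA in the clone pairings, 228 between the NES-AURKA clones, 11 between the NLS-AURKA clones, 5 between NES-Empty and Empty and 7 between NLS-Empty and Empty. Without libraries D and A, 20 genes were called in the NES-AURKA against WT-AURKA pairings. A letter-set term gave 5 genes for NES-Empty and 3 for NLS-Empty against Empty, and no filter and median-of-ratios scaling 1 each for NLS-Empty. For NES-AURKA against WT-AURKA the share of higher calls was 32.1% in all, 52.6% with median-of-ratios scaling, 43.1% with no filter and 44.8% in the I to Z libraries.

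Leaving out each line in turn gave 915 (without NLS-Empty) to 2669 genes for AURKA against control lines, 2250 (without NLS-AURKA c2) to 5473 for NLS-AURKA against NES-AURKA, 2509 (without NLS-AURKA c2) to 6267 for NLS-AURKA against WT-AURKA, and 20 (without WT-AURKA c2) to 2433 (without NES-AURKA c1) for NES-AURKA against WT-AURKA.
With each library left out, the pairings gave 152 (without R; 165 without Q) to 329 (without D) for NLS-AURKA against WT-AURKA and 5 (without Q; 7 without R) to 16 (without D) for NES-AURKA against WT-AURKA, WT-AURKA against Empty gave 198 (without Q; 199 without R) to 360 (without D), NES-Empty against Empty 1 (without E, I or L) to 2, and NLS-Empty against Empty 0 to 1 (without E).

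In the A to H libraries AURKA differed by 0.23 between AURKA and control lines, 1.16 between NLS-AURKA and NES-AURKA (adjusted p = 0.0652) and -1.51 between NES-AURKA and WT-AURKA. For AURKA itself, the log2 difference between AURKA and control lines was -0.86. It passed with matched control lines (adjusted p = 0.0179), a fit without the spread between control lines and between constructs. As lines were left out it lay between -1.06 (without NLS-AURKA c2, where it passed, adjusted p = 0.0479) and -0.64 (without WT-AURKA c2). NLS-AURKA against NES-AURKA stayed at 1.005 and did not pass with no filter (adjusted p = 0.0883), and lay between 0.80 (without NES-AURKA c2, adjusted p = 0.0568) and 1.21 (without NES-AURKA c1). Both WT-AURKA clones against Empty passed in the I to Z libraries (mean -2.22, larger adjusted p = 0.000112) and without libraries D and A (-2.10, 0.0011), and lay between -2.10 (without D, adjusted p = 0.0021) and -1.45 (without P) as libraries were left out. Uncalled differences that changed sign were those of the NLS-AURKA clones against NLS-Empty (-0.20 in the I to Z libraries; -0.072 without G to 0.34 without X), WT-AURKA c2 against c1 (0.0021 in the I to Z libraries and without libraries D and A; -1.31 without P to 0.0021 without D), NES-Empty against Empty (0.029 in the I to Z libraries; -0.18 without E to 0.15 without C) and NLS-AURKA c3 against c2 (-0.63 without X to 0.079 without W).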

Other observations

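The gene families, the S phase test, the use of the I to Z list tests for the histone genes and the other assignments of samples were chosen after the results had been seen; the tests of RNA without poly(A) tails, of the letter sets in the histone genes and of a shared origin of clones were fixed before their results were.

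X-linked cancer-testis genes, normally transcribed in germ cells, were among the lowest genes in NLS-AURKA against the other AURKA clones. PAGE5 was at 78.7 ± 2.99 RPKM in WT-AURKA, 52.9 ± 8.55 RPKM in NES-AURKA and 2.62 ± 0.0108 RPKM in NLS-AURKA (SD, n = 2 lines each), and MAGEC1 at 14.5 ± 2.29, 14.1 ± 1.28 and 0.333 ± 0.237 RPKM. In the control lines Empty and NES-Empty PAGE5 was listed at 0 and 0.0318 RPKM. Its low level in NLS-AURKA is therefore no fall below these controls, and WT-AURKA and NES-AURKA were far above them. Of 17 family members 7 had been named for their change before the family was drawn up, and these 7 were left out of the test. Of the other 10, 7 were lower and 1 higher in NLS-AURKA than in NES-AURKA (camera adjusted p = 0.00112, adjusted p = 0.0565 with an estimated correlation), and 8 were lower and 0 higher than in WT-AURKA (camera adjusted p = 3.98e-06, adjusted p = 0.0224 with an estimated correlation). In NES-AURKA 4 were lower and 0 higher than in WT-AURKA (camera adjusted p = 0.0508). Between AURKA and control lines, a contrast that pools NLS-AURKA with WT-AURKA and NES-AURKA, 0 were called (camera adjusted p = 0.0726). Many members have near-identical copies, so single values are uncertain. Members kept in the test may share reads with those left out, so it is not independent of the genes named before. All 9 pregnancy-specific glycoprotein genes tested, normally placental, were lower in AURKA than in control lines, and the 7 not named before had a median of -0.92 (camera adjusted p = 2.59e-09, adjusted p = 0.0130 with an estimated correlation). PSG5 was at 0.371 ± 0.0798 RPKM (n = 6 lines) against 10.9 ± 3.31 RPKM (n = 3), and none of the 9 was called between constructs. These genes are also alike in sequence, and were chosen after 2 of them had been named, so the test of the other 7 is not independent of those 2.

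Of the 10 keratin genes tested other than KRT81 and KRT86, 6 were lower and 0 higher in NLS-AURKA than in NES-AURKA (camera adjusted p = 2.49e-05, adjusted p = 0.0565 with an estimated correlation), and 5 were lower and 0 higher than in WT-AURKA (camera adjusted p = 0.00319, adjusted p = 0.172 with an estimated correlation). The family was drawn up after KRT81 and KRT86 had been named, and relatives alike in sequence may share reads, so this test is not independent of them. Besides KRT81, the simple epithelial keratin gene KRT7 fell by 2.75 on the log2 scale against NES-AURKA (SE 0.22, limma adjusted p = 7.43e-05) and KRT80 by 1.77 (SE 0.13, adjusted p = 4.70e-05), whereas KRT18 differed by -0.12 (SE 0.11, adjusted p = 0.436). Of 4 metallothionein genes tested, which bind zinc and copper, MT1E, MT1X and MT2A rose by 1.21, 1.39 and 0.98 (SE 0.20, 0.14 and 0.11) in NLS-AURKA against NES-AURKA and MT1A fell by 0.56 (SE 0.15; camera adjusted p = 0.0643 for the family). Against WT-AURKA, MT1X and MT2A rose by 1.49 and 0.47 (adjusted p = 0.000137 and 0.00974), MT1A fell by 0.80 (adjusted p = 0.00406) and MT1E differed by 0.38 (adjusted p = 0.170; camera adjusted p = 0.289 for the family). Unfolded protein and integrated stress genes in NLS-AURKA were lower as a list in the I to Z libraries, against NES-AURKA (median -0.48, camera adjusted p = 0.00281, adjusted p = 0.673 with an estimated correlation) and against WT-AURKA (median -0.57, adjusted p = 0.000216, adjusted p = 0.791 with an estimated correlation), and did not pass in all libraries (adjusted p = 0.117 and 0.0567, and adjusted p = 0.994 and 0.959 with an estimated correlation).

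Histone genes were higher in the NLS-AURKA clones, in which an effect of the guide and cDNA label was not tested and stays open. Capture of RNA without poly(A) tails would raise other RNAs of that kind too, and 7 such RNAs had median differences between NLS-AURKA and NES-AURKA libraries of -0.96 in the A to H set and -0.07 in the I to Z set on the log2 scale, which argues against it. An effect of the letter sets is argued against by the I to Z libraries alone, where 14 of the 15 histone genes were higher (4 against 4) and the list passed against NES-AURKA (camera adjusted p = 2.47e-06, adjusted p = 0.333 with an estimated correlation) and WT-AURKA (adjusted p = 5.37e-06, adjusted p = 0.487 with an estimated correlation). In the A to H libraries (2 against 2) 10 of 15 were higher (list adjusted p = 0.0580), below the limit set in advance, but a difference between the sets cannot make one within a set, which that limit left out. More cells in S phase may also account for it, but the median log2 fold change of DNA replication genes was 0.0303 against NES-AURKA and 0.08 against WT-AURKA, under the 0.1 it needs, and 0.12 (camera adjusted p = 0.299) and 0.35 (adjusted p = 0.000216, adjusted p = 0.881 with an estimated correlation) in the I to Z libraries, above it, so it stays open.

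No gene was called by limma between the 2 WT-AURKA clones (57 at an unadjusted p under 0.05) or the 2 NLS-AURKA clones (114), in a fit whose spread includes the difference between letter sets. With a letter-set term 164 and 486 passed unadjusted and 0 were called, and in the I to Z libraries 0 and 11 were called. Clones from 1 origin would differ in no more genes that are on in one and off in the other than control lines do. With at least 5 RPKM in one and under 0.5 RPKM in the other in the I to Z libraries, there were 0 such genes between the WT-AURKA clones, 0 between the NLS-AURKA clones, 0 to 1 between control lines, 4 between the NES-AURKA clones and 2 to 33 between clones of different constructs. These counts are consistent with a shared origin within the WT-AURKA and NLS-AURKA pairs, as a hypothesis. If it held, those constructs would count 1 independent isolate each, and lines that differ little without it stay possible.

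Other assignments of the samples were tried for each count. For AURKA against control lines, 1 of the 84 splits of the 9 lines gave as many genes as the 2423 of the real one, and the highest other gave 758 (both WT-AURKA clones and NES-AURKA c1 against the rest). In the clone pairings, 1 of 100 assignments of libraries to lines gave as many for NLS-AURKA against NES-AURKA (205, highest other 0), for NLS-AURKA against WT-AURKA (275, highest other 3) and for NES-AURKA against WT-AURKA (12, highest other 0). Against matched controls the numbers were 1 of 100 for NES-AURKA (214, highest other 89) and 1 of 100 for NLS-AURKA (568, highest other 3). For WT-AURKA against Empty, 2 of 100 gave as many (330, highest other 335), the other one exchanging libraries between the WT-AURKA clones alone. The share of 1 in 84 is under 0.05 if the 9 lines are independent, but only 20 splits keep the WT-AURKA and NLS-AURKA pairs together (highest other 758) and 10 keep all 3 pairs together (highest other 0), too few for a share under 0.05. The assignments of libraries show that libraries of a construct resemble each other. For libraries of a line they do not show it in the WT-AURKA pair, where exchanging libraries between the clones gave 335. The assignment that gave 89 kept the NES-AURKA c1 libraries F, S and T together. It set them against mixed libraries of NES-AURKA c2 and NES-Empty, so there libraries of a line resembled each other. The lines of each of those 6 comparisons form 3 groupings, too few for a share under 0.05. The 10 splits of 2 lines with 3 libraries each are too few for a share under 0.05: the NES-AURKA clones had 136 genes (highest other 10, 1 split as large), the NLS-AURKA clones 0 (highest other 5, 10 splits as large), NES-Empty and Empty 2 (highest other 0, 1 split as large), and NLS-Empty and Empty 0 (highest other 0, 10 splits as large).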
